A study of Mus musculus with 6 samples.

How the data were processed

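Total RNA was extracted with a spin-column kit from fetal mouse livers at E18.5, labelled with biotin and hybridised by the standard Affymetrix procedure, per the labels' protocols. The arrays are mouse 3' expression arrays, and each of the 6 samples is 1 array. The design text speaks of 3 livers in each group and the titles carry different numbers, so each array was taken as 1 replicate. Nothing says more on how the livers were collected or whether they came from shared litters, so p values measure the spread between these arrays. The groups are control, with 1 flanked Hnf4 allele and the AlfpCre transgene, and null, with both alleles flanked and the transgene, from the strain label.

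The deposited values are probe-set intensities on a linear scale, 1 per probe set and array, as the values themselves show: they run from below 0 to 12608, and between 0.908% and 1.34% of each array's values are below 0, so some background or mismatch signal had been subtracted before deposit. The summarisation of probes to probe sets, the background step, the scaling between arrays and the software are not given in the sources used here. The medians of the 6 arrays were already close when deposited, at 91.8 to 99.5. No signal-detection call was used. The array number limits the precision, and the depth of a sequencing library has no counterpart here.

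Values below 0 were set to 0, 32 was added and log2 taken. Array medians of these log2 values differed by at most 0.0877, under the tolerance of 0.2 set in advance, so the deposited scaling was kept and no further normalization was done. Of 45101 probe sets, 64 control probe sets were left out of the tests and 45037 were tested. The platform annotation gave 1 gene symbol to 34945 of these, several to 932 and none to 9160, and 34741 matched a gene of the reference table (assembly GRCm38.p6) by Entrez number, which changed 0 symbols. The files name no genome build, so no coordinates are given and that table served only for names and for the order of neighbouring genes. No gene was named from a probe set with several symbols. A gene was represented by the probe set with 1 symbol that had the highest mean log2 value over the 6 arrays, which left 18193 genes. No 2 arrays held identical values.

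The 2 groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, all 6 arrays and no covariate, and Benjamini-Hochberg adjustment over the 45037 probe sets with a threshold of 0.05. Tests are two-sided unless stated. For 32 gene lists of liver functions, other cell types and stress responses, limma's camera compared each list with all other genes at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, whose directional p asks whether the genes of a list move on balance 1 way, were run beside it. Of the 21 lists that camera called, 16 lower and 5 higher, 8 held with an estimated correlation, and fry called 22. Some list members have no singly named probe set here and were not analysed.

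The lists, the design, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names Hnf4a, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose brighter group lies above the median of all probe sets, and, for each list with a called member, up to 3 members with the smallest adjusted p and the called member with the smallest adjusted p in the opposite direction. Xist and Y-linked probe sets were read only for embryo sex.

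The alternatives were quantile normalization, centring of array medians, a pseudocount of 1 or 100, only probe sets above the median level, no intensity trend, array weights, the mean of all probe sets of a gene, a change of at least 2-fold, probe sets in place of genes, a block for the run of the title numbers, the 4 arrays other than Control_8 and Null_61 alone, a term for embryo sex, and each array left out in turn. All 10 splits of the 6 arrays into 3 and 3 were also fitted. An exact two-sided permutation test of 3 arrays against 3 cannot go below p = 0.1, so none is given.

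The fit was tested on simulated data for the comparison of null with control. Of 45037 probe sets 200 were changed, all drawn from those above the median control level. On the log2 scale, 90% of changes of 1 and 99% of changes of 2 were recovered, with 18 false calls. Changes of dimmer probe sets were not simulated. The noise was normal and independent, with no effect of run or sex. In simulated data for 18193 genes, camera gave a p under 0.05 for 0.5% of 200 random lists of 20 genes, and found a shifted list. The simulated genes were independent of each other. The 0.5% is therefore no measure of false calls in lists whose genes are correlated.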

Results

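The arrays profiled total RNA from fetal mouse livers at E18.5, shortly before birth, and compared livers meant to lack HNF4 alpha with livers that keep it. HNF4 alpha, the product of Hnf4a, is a nuclear receptor that binds the promoters of many genes of the hepatocyte, the main epithelial cell of the liver. In the 3 control livers the strain label gives 1 loxP-flanked and 1 unflanked Hnf4 allele together with the AlfpCre transgene, and in the 3 null livers both alleles are flanked. AlfpCre expresses Cre recombinase from albumin and alpha-fetoprotein regulatory elements, so recombination is directed to the hepatocyte lineage, and the whole livers also hold blood-forming, endothelial, mesenchymal and other cells. The arrays are named here as in their titles, by group and number, as Control_8, Control_1192 and Control_1193 and Null_61, Null_1191 and Null_1195. Each array gave 1 intensity per probe set, with array medians from 91.8 to 99.5 and the highest values from 11302 to 12608. Values with ± are means and SD of the deposited intensity over 3 arrays, and log2 changes are null minus control after adding a pseudocount of 32, which understates the change of dim genes (folds are taken from these log2 changes, and none is given where a group's mean lies below 99.5, the highest array median). Adjusted p values come from limma. With 3 arrays in each group, their number limits the precision.

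Hnf4a signal was lower in the null livers but far from absent, at between 62.1% and 71.8% of the control level in its 4 probe sets. The brightest, 1427001_s_at, which stands for the gene in the counts, read 2767 ± 142 in the controls and 2039 ± 649 in the nulls, a log2 change of -0.48 with a standard error of 0.19 that did not pass the test (adjusted p = 0.194). In that probe set Null_1195 read 2778, inside the control range of 2607 to 2877, while Null_61 read 1778 and Null_1191 read 1562. Probe set 1421983_s_at fell from 1155 ± 40.6 to 718 ± 166 (log2 change -0.69, standard error 0.17, adjusted p = 0.0434) and 1450447_at fell from 517 ± 22.9 to 346 ± 60.9 (log2 change -0.55, standard error 0.14, adjusted p = 0.0488). Probe set 1427000_at read 1865 ± 81.1 and 1291 ± 269, with an adjusted p of 0.0785. It was called with the number run as a block (0.0251), with array weights (0.0160) and without Null_61 (0.0260). In 3 of the 4 probe sets all 3 nulls lay below all 3 controls. Both calls were marginal: the call of 1450447_at was lost without Control_8, Control_1192 or Control_1193 or Null_1191 or Null_1195 (adjusted p = 0.157, 0.169, 0.121, 0.161 and 0.128), and that of 1421983_s_at without Control_8, Control_1192 or Control_1193 or Null_1191 (0.142, 0.14, 0.126 and 0.0694). Without Null_1195 the brightest probe set reached -0.72 with an adjusted p of 0.00589. With all arrays kept, the calls of 1421983_s_at and 1450447_at were also lost with embryo sex as a term (adjusted p = 0.111 and 0.126), quantile normalization (0.118 and 0.130), no intensity trend (0.0619 and 0.0653) and a pseudocount of 1 (0.0524 and 0.0509), and that of 1450447_at with centred array medians (0.0640). In the 4 arrays without Control_8 and Null_61 the adjusted p of 1421983_s_at was 0.0506. Where these probe sets lie relative to the loxP-flanked part is not given in the sources used here, so a retained signal checks the labels only in part.

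**Figure D1:**
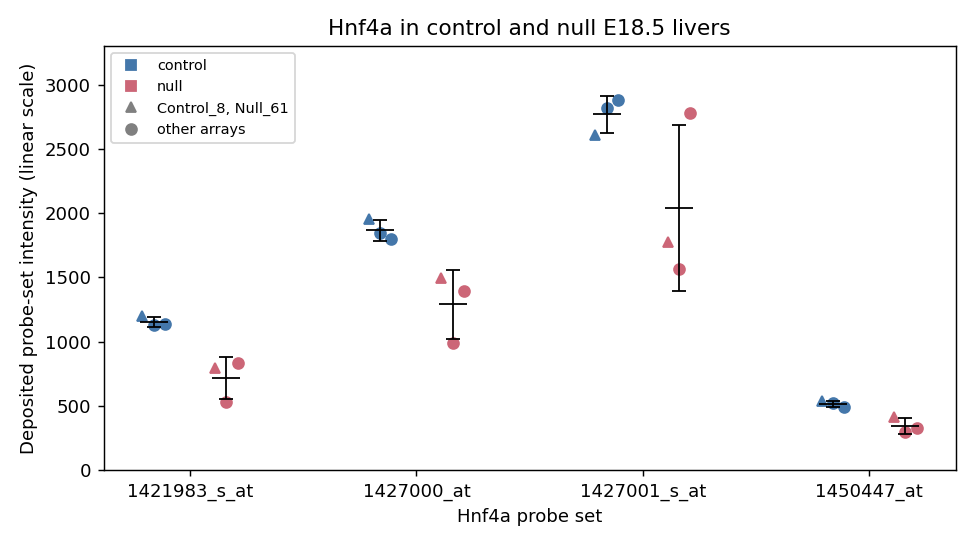
Deposited linear intensity of the 4 Hnf4a probe sets in the 3 control and 3 null livers, with 1 point per array, the group mean as a horizontal bar and its SD as whiskers; triangles are Control_8 and Null_61, circles the other 4 arrays. Group means of the nulls are lower in every probe set, and Null_1195 reads 2778 in 1427001_s_at, within the controls.

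Transcripts typical of hepatocytes fell widely in the null livers, and falls outnumbered rises. Of 18193 genes measured, 1428 fell and 283 rose at an adjusted p under 0.05, and at a change of at least 4-fold the counts were 248 and 11. Several bright transcripts fell to the background of the arrays. Cyp2d26, a cytochrome P450, read 3016 ± 137 in the controls and Hrg, the plasma histidine-rich glycoprotein, read 2724 ± 346, and all 3 null arrays listed both below 0, so no fold is given (adjusted p = 2.6e-08 and 6.4e-08). Since values below 0 were set to 0, the null values of these genes were equal in the test. Their p values hold no spread between the null livers. Apob, the structural apolipoprotein of very low and low density lipoproteins, went from 3143 ± 1236 to 7.17 ± 3.96. The rest of the 10 falls with the largest size at this pseudocount were Hsd17b13, Itih4, F13b, Abcb11, Igfbp2, Ces1c and F12. The size and order of falls to the background are set by the pseudocount: with a pseudocount of 1 or 100 the log2 change was -8.60 or -4.83 for Apob, -10.51 or -3.96 for Abcb11 and -6.56 or -4.95 for Itih4. The other probe set of Hsd17b13 was not called, and with the mean of probe sets Hsd17b13 was at -2.78 and Apob at -4.50. Igfbp2, which encodes a binding protein of insulin-like growth factors, fell from 6022 ± 534 to 110 ± 32.5.

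Among the rises, Serpina6, which encodes corticosteroid-binding globulin, went from 199 ± 150 to 5921 ± 659 (log2 change 4.99, standard error 0.52, adjusted p = 0.000455), and the log2 change was 4.26 without Control_1192. Nnat, the imprinted gene of the membrane protein neuronatin, rose from 67.3 ± 25.5 to 2512 ± 586, by 4.68 on the log2 scale with a standard error of 0.22. Ldhb, the heart-type subunit of lactate dehydrogenase, rose from 136 ± 8.56 to 1257 ± 138, and its 3 other probe sets rose too. The other probe sets of Tnfrsf19 (2) and Gabra4 (1) were not called, and with the mean of probe sets these genes had log2 changes of 0.95 and 1.03 in place of 2.21 and 2.04. Dnajc12, a J-domain co-chaperone gene, rose from 339 ± 10.9 to 1684 ± 330. The rest of the 10 rises with the largest size at this pseudocount were Meis3, Hcrt, Nat14, Pla2g5, Tnfrsf19 and Gabra4. Meis3 and Hcrt read -543 ± 60.2 and -440 ± 227 in the controls and 278 ± 141 and 202 ± 67.0 in the nulls, so no fold is given for either. Pla2g5 read 0.144 ± 62.8 in the controls and 187 ± 41.3 in the nulls, and its call was lost without Control_1192 (adjusted p = 0.0600) or Null_1191 (0.0567) and with a pseudocount of 1 (0.0704).

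The groups were separated along the first principal component, which held 56.3% of the variance, and arrays correlated at 0.969 to 0.981 within the controls, 0.941 to 0.974 within the nulls and 0.904 to 0.926 between groups, across probe sets, which are not independent replicates. In each of the 1711 called genes all 3 nulls lay on 1 side of all 3 controls. In all, 5641 genes (31.0%) had groups that did not overlap, where chance gives 10%, and 4416 passed an unadjusted p of 0.05. The falling share of the calls was 83.5%, and with quantile normalization it was 66.0%, from 617 rises and 1196 falls. The number of rises depended on single arrays: it was 129 without Control_8, 98 without Control_1192, 129 without Control_1193, 558 without Null_61, 135 without Null_1191 and 156 without Null_1195, and the number of falls was 906 without Control_1192.

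Control_8 and Null_61 lie in another run of title numbers and stood apart from the other 4 arrays. The control probe set for the 5' part of 18S ribosomal RNA read 42.1 in Control_8 and 33.5 in Null_61, against 449 to 616 in the other arrays, and both lay apart on the second principal component, which held 22.4% of the variance. The labels do not say that the numbers mark a batch. With the number run as a block, 747 genes rose and 2021 fell, among them all 283 and 1428 of the fit without it. Within the 4 other arrays alone, 424 rose and 1565 fell, and of these 367 and 1525 had the same direction in Null_61 against Control_8, a pair too small for a test. Xist and Y-linked probe sets read Control_8, Null_1191 and Null_1195 as female and the other 3 as male. Within each number run, embryo sex therefore went with the group, in opposite directions. With sex as a term, 170 genes rose and 1102 fell.

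**Figure D2:**
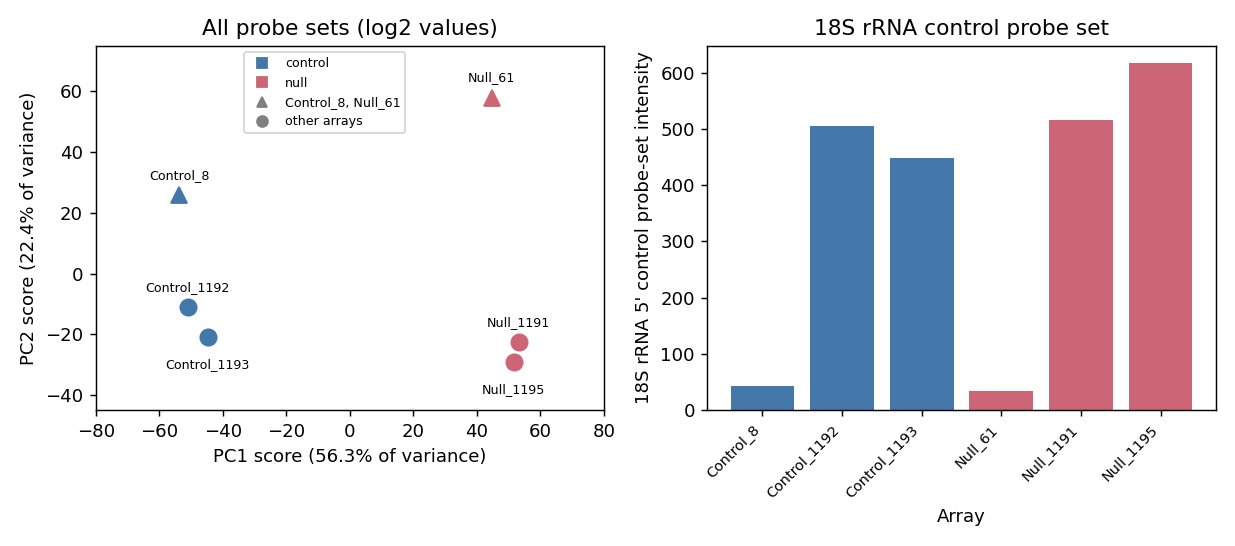
Left, scores of the 6 arrays on the first and second principal components of the log2 values of all probe sets, which hold 56.3% and 22.4% of the variance; right, linear intensity of the control probe set for the 5' part of 18S ribosomal RNA, 1 bar per array. Controls and nulls are apart on the first component, and Control_8 and Null_61 have the lowest 18S readings, 42.1 and 33.5.

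Secreted liver proteins were the first of the gene groups asked about. Of 22 measured plasma protein genes 17 fell and 1 rose, of 16 coagulation genes 13 fell, of 16 complement genes 12 fell, and of 16 genes of apolipoproteins and lipoprotein secretion 14 fell. Median log2 changes of these lists were -0.91, -1.54, -2.06 and -1.87. Itih4, a heavy chain of the inter-alpha-trypsin inhibitors, fell from 4447 ± 207 to 46.7 ± 9.73. Hpx and Hp, for the plasma scavengers of heme and hemoglobin, fell 11.8-fold and 8.16-fold. The member that rose was Serpina6. F13b, for a subunit of the fibrin-crosslinking factor, fell from 1997 ± 72.0 to 8.99 ± 1.93, and F10 from 2903 ± 150 to 65.2 ± 6.28 (log2 change -4.92, and -2.79 with the mean of its probe sets). F12, which starts the contact pathway, went from 1202 ± 93.2 to values below 0 in all 3 nulls. The complement gene Cfb fell from 2600 ± 98.8 to 92 ± 11.7. Cfi and Hc fell 11.9-fold and 9.06-fold. Apoc2, an activator of lipoprotein lipase, fell 13.1-fold, and Lcat, which esterifies plasma cholesterol, fell 6.79-fold. Adjusted over the list alone, 19, 13, 14 and 15 members fell. Camera called all 4 lists lower with its preset correlation (adjusted p from 3.15e-18 to 5.88e-15), and the calls held with an estimated correlation (adjusted p from 0.0225 to 0.0386). Alb, the gene of albumin, had a log2 change of 0.02 and did not pass the test. Its signal lies near the top of the arrays' range, where a change is hard to see.

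Metabolic genes of the hepatocyte also fell in large number. Of 30 measured genes of xenobiotic and steroid metabolism 24 fell, with a median log2 change of -2.71, and of 24 genes of the urea cycle and amino acid metabolism 19 fell, with a median of -2.57. Bile acid synthesis and transport had 15 falls among 19 measured genes with a median of -1.48, and glucose and glycogen metabolism had 9 among 14 with a median of -1.78. Cyp2d10, a cytochrome P450 like Cyp2d26, went from 1023 ± 55.2 to values below 0 in all 3 nulls, and Ephx2, the soluble epoxide hydrolase, fell from 1321 ± 75.8 to 84.7 ± 7.51. Otc, the urea cycle enzyme that makes citrulline, fell from 1256 ± 100 to 37.9 ± 13.8 (log2 change -4.22, and -3.28 with the mean of its probe sets, with 1 of its 2 other probe sets called). Agxt, which detoxifies glyoxylate, fell from 1250 ± 188 to 67.3 ± 7.95, and Fah, the last enzyme of tyrosine breakdown, 12-fold. Abcb11, the pump that exports bile salts into the canaliculus, went from 1480 ± 321 to values below 0 in all 3 nulls. Slc10a1, which takes bile salts up from blood, fell from 2845 ± 87.0 to 77.8 ± 15.2. Hsd3b7, an early enzyme of bile acid synthesis, fell 11-fold. The gluconeogenic genes Fbp1 and Pcx fell 17.3-fold and 8.59-fold, and G6pc fell from 1274 ± 301 to 78.2 ± 7.30. Adjusted over the list alone, 26, 20, 15 and 9 members of these lists fell, and 1 bile acid gene rose. Camera called all 4 lower (adjusted p from 8.93e-28 to 1.19e-10), and the calls held with an estimated correlation (adjusted p from 0.0225 to 0.0459).

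**Figure D3:**
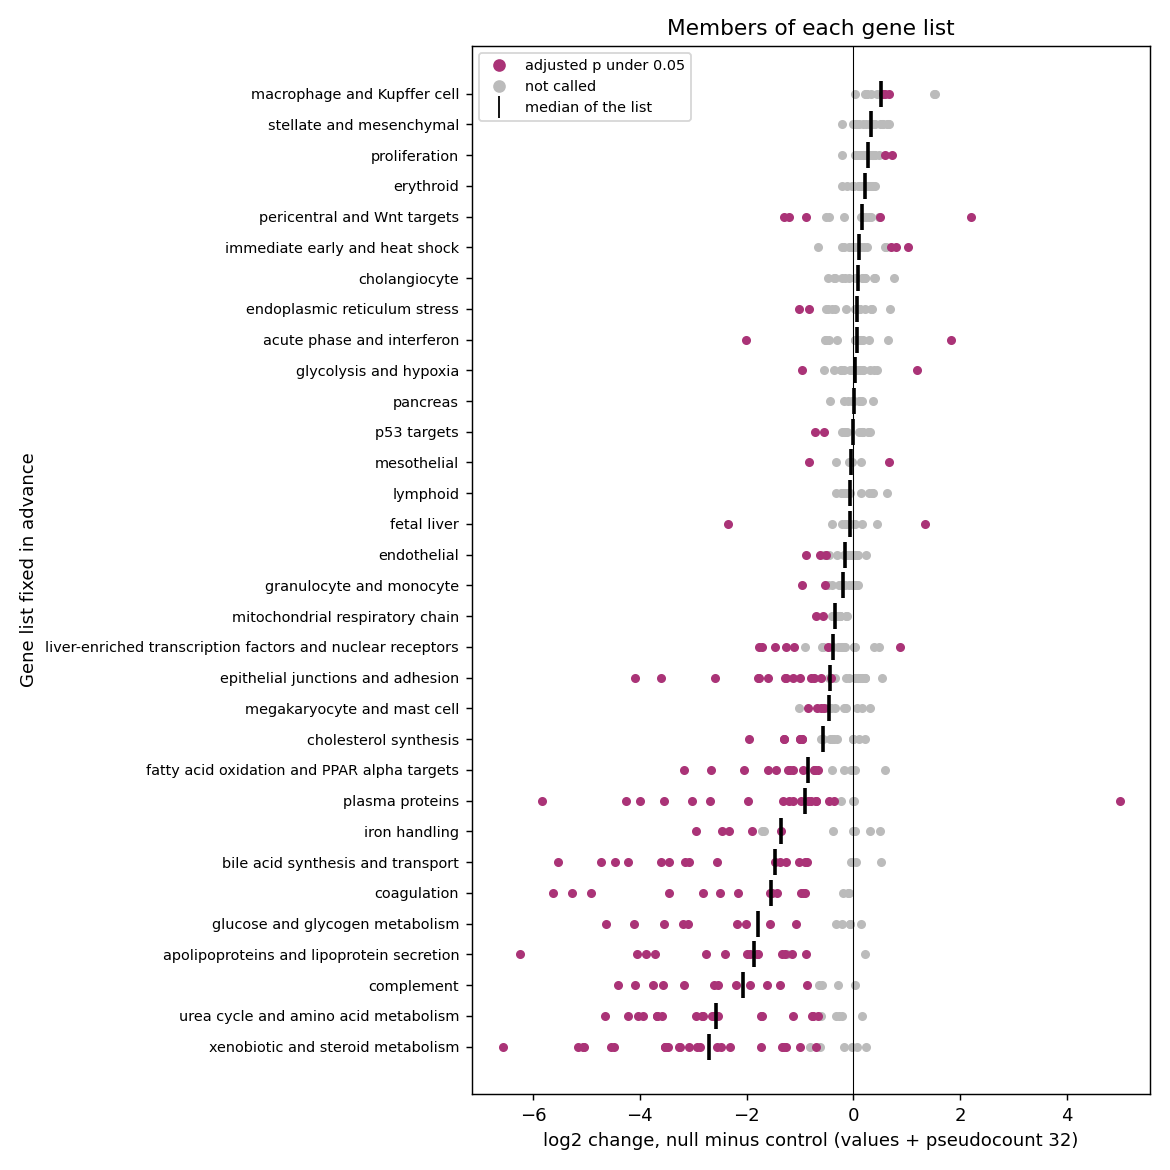
Log2 change, null minus control, of every measured member of the 32 gene lists fixed in advance, with 1 row per list in the order of the medians; coloured points passed an adjusted p of 0.05, grey points did not, and the black bar is the median of the list. The lowest median is -2.71, for xenobiotic and steroid metabolism, and the highest is 0.53, for markers of macrophages.

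Genes of lipid oxidation, cholesterol synthesis and iron handling fell in part. Of 18 genes of fatty acid oxidation and targets of PPAR alpha 12 fell, among them Fabp1, the liver fatty acid-binding protein, 6.38-fold, Ehhadh, the peroxisomal bifunctional enzyme, from 815 ± 235 to 60.8 ± 20.5. Angptl4, an inhibitor of lipoprotein lipase, fell 4.14-fold (log2 change -2.05, and -0.96 with the mean of its probe sets, the other probe set not being called). Of 17 genes of cholesterol synthesis 7 fell, with Insig1, a brake on sterol regulation, down 3.86-fold, Lss, which makes lanosterol, 2.47-fold (1 of its 2 other probe sets called), and Fdps, which makes farnesyl diphosphate, 2.0-fold (log2 change -0.40 with the mean of its probe sets, the other probe set not being called). The median of the cholesterol list's members was -0.85 in Null_61, -0.70 in Null_1191 and -0.32 in Null_1195. Of 13 iron genes 5 fell, with examples in Hjv, Tfr2 and Tmprss6, all of which act on the control of hepcidin: Hjv went from 289 ± 30.1 to 26.0 ± 4.54, and Tfr2 and Tmprss6 fell 5.04-fold and 3.75-fold. Null_61 stood apart in the iron list, with a median of -0.44 over its members against -1.47 in Null_1191 and -1.36 in Null_1195. Adjusted over the list alone, 13, 11 and 7 members fell, and 1 gene of fatty acid oxidation rose. Camera called all 3 lists lower (adjusted p = 6.43e-10, 2.74e-05 and 9.74e-05), and none held with an estimated correlation (adjusted p = 0.0749, 0.19 and 0.19).

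Among liver-enriched transcription factors and nuclear receptors, 6 of 23 measured genes fell and 1 rose. Cebpa, a factor of hepatocyte differentiation, fell from 1562 ± 45.6 to 464 ± 95, Nr1i2, the pregnane X receptor, from 247 ± 67.0 to 48.4 ± 9.06, and Creb3l3, a membrane-bound factor of the hepatic fasting response, fell 2.17-fold. Foxa1, a pioneer factor of liver development, rose from 85.4 ± 10.5 to 186 ± 56.5, a call that was lost without Control_8, Control_1192 or Control_1193 or Null_1195 (adjusted p = 0.0943, 0.0847, 0.0748 and 0.0600). The list's members had medians of -0.28 in Null_61, -0.58 in Null_1191 and -0.20 in Null_1195, and when adjusted over the list alone, 9 fell and 2 rose. Of 30 genes of epithelial junctions and adhesion 14 fell. Cldn1, a tight junction protein, fell from 2940 ± 89.6 to 144 ± 13.4 (log2 change -4.08, and -2.76 with the mean of its probe sets, with 2 of its 3 other probe sets called). Cdh1, the adherens junction protein E-cadherin, fell from 934 ± 130 to 52.4 ± 38.8, and Gjb1, a gap junction protein of hepatocytes, 6.03-fold. The number that fell adjusted over the list alone was 16. Junction and adhesion genes are known to have been a subject of the study these arrays belong to, so this list is not independent evidence of its direction. Camera called both lists lower (adjusted p = 0.00111 and 1.78e-06), and neither held with an estimated correlation (adjusted p = 0.252 and 0.243).

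Markers of other cells of the liver moved little in their list medians beside these changes, and not in 1 direction. Single members that did not pass the test changed more, with log2 changes up to 1.54 among macrophage genes and down to -1.02 among megakaryocyte genes. Of 13 macrophage and Kupffer cell genes 3 rose, namely Timd4, Clec4f and Adgre1, by 1.51-fold, 1.47-fold and 1.60-fold, and the list had a median log2 change of 0.53. Against the mean of the controls, the median of its members was 0.82 in Null_61, 0.34 in Null_1191 and 0.35 in Null_1195. All 3 of these calls were lost without Control_1192 (adjusted p = 0.119, 0.131 and 0.145) or Control_1193 (0.113, 0.113 and 0.128), those of Timd4 and Clec4f also without Null_1191 (0.0928 and 0.0525), those of Clec4f and Adgre1 without Null_1195 (0.0808 and 0.0639), and that of Adgre1 without Control_8 (0.0547) or with centred array medians (0.0524). With embryo sex, which is unequal between the groups, as a term, all 3 were lost (adjusted p = 0.0734, 0.0850 and 0.0699). Of 14 megakaryocyte and mast cell genes 4 fell, with the platelet genes Pf4, Gp1bb and Itga2b down 1.46-fold, 1.81-fold and 1.53-fold, and the median was -0.46. These 3 calls were lost without Control_8 (0.0800, 0.0890 and 0.138), Control_1192 (0.0946, 0.113 and 0.149) or Null_1191 (0.0791, 0.0928 and 0.130). The call of Gp1bb was lost also without Null_1195 (0.0729) and that of Itga2b without Control_1193 (0.0598). The call of Gp1bb was lost with the mean of its probe sets (log2 change -0.18, adjusted p = 0.411, the other probe set not being called), and those of Gp1bb and Itga2b with embryo sex as a term (0.0638 and 0.0677). Calls were also lost by Pf4 and Itga2b with quantile normalization (0.0892 and 0.0981) and in the 4 arrays without Control_8 and Null_61 (0.0532 and 0.0873), and by Itga2b without an intensity trend (0.0510). Of 18 endothelial genes 3 fell, with Stab2, a scavenger receptor of liver sinusoids, down 1.85-fold, and the receptors of vessel growth Kdr, down 1.54-fold, and Tek, from 93.3 ± 11.1 to 56.1 ± 3.31. The endothelial members had medians of -0.01 in Null_61, -0.28 in Null_1191 and -0.22 in Null_1195. The call of Kdr was lost without Control_8, Control_1192 or Control_1193 or Null_1191 (0.108, 0.134, 0.0658 and 0.107), that of Tek without any 1 of the 6 arrays (between 0.0505 without Null_61 and 0.173 without Control_1192). That of the list, whose adjusted p was 0.0325, was lost without Control_8, Null_1191 or Null_1195 (0.0833, 0.109 and 0.0867) and with an estimated correlation (0.387). Kdr was also lost with quantile normalization (0.0589), Tek with embryo sex as a term (0.0898), no intensity trend (0.0502) and a pseudocount of 1 (0.0539), and both in the 4 arrays without Control_8 and Null_61 (0.0735 and 0.0979). None of the 20 erythroid or 20 stellate and mesenchymal genes passed limma's test (7 and 6 were higher at an unadjusted p under 0.05, none lower). Camera called both lists higher, with medians of 0.22 and 0.33 and adjusted p values of 0.0026 and 0.00141, and neither call held with an estimated correlation (adjusted p = 0.19 and 0.266). The stellate list was not called by fry (adjusted p = 0.0914) or in the 4 arrays without Control_8 and Null_61 (median 0.14, adjusted p = 0.0607), and its members had medians of 0.44 in Null_61, 0.09 in Null_1191 and 0.18 in Null_1195. Adjusted over the list alone, 6 macrophage genes rose, 6 megakaryocyte and 5 endothelial genes fell, and no erythroid or stellate gene was called. Camera gave adjusted p values of 2.84e-05 for macrophages and 0.0051 for megakaryocytes, and neither call held with an estimated correlation (adjusted p = 0.19 for both).

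Of 24 proliferation genes 2 rose, Birc5, which encodes survivin, 1.66-fold and Rrm2, a subunit of ribonucleotide reductase, 1.51-fold, and 3 rose when adjusted over the list alone. The list median was 0.27 and camera called it higher (adjusted p = 1.35e-05), a call not held with an estimated correlation (adjusted p = 0.243). The call of Rrm2 was lost without any 1 of Control_8, Control_1192 or Control_1193 or Null_1191 or Null_1195 (adjusted p = 0.134, 0.0611, 0.120, 0.135 and 0.0928), with embryo sex as a term (0.0945), without an intensity trend (0.0662) and with the mean of its probe sets (0.0670), neither of the 2 others being called. Of 17 genes of the mitochondrial respiratory chain 2 fell, Sdhb and Sdha of complex II, 1.62-fold and 1.48-fold, and 11 fell when adjusted over the list alone, with a median of -0.34 (camera adjusted p = 1.35e-05, and 0.0809 with an estimated correlation). The call of Sdha was lost without Control_8 (adjusted p = 0.0552) or Control_1192 (0.0503), with quantile normalization (0.0736) and with the mean of its probe sets (log2 change -0.21, adjusted p = 0.177). Of its 3 other probe sets 1 was called. Of 16 immediate early and heat shock genes 3 rose, the early response genes Junb and Egr1, 1.73-fold and 2.03-fold, and Fos, from 38.4 ± 2.81 to 83.4 ± 11.3, with 4 higher and 1 lower when adjusted over the list alone. That list was called higher (adjusted p = 0.0322) but not with an estimated correlation (adjusted p = 0.19) or without Control_1193 (0.137), with quantile normalization (0.0541) or above the median level (0.0657). The call of Fos was lost without Control_1193 (0.0550) and that of Egr1 without Control_8, Control_1193 or Null_1195 (0.0702, 0.0892 and 0.0837).

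The other 11 lists were not called by camera. Of 15 pericentral genes and Wnt targets 3 fell and 2 rose: Rgn and Lect2 fell 2.46-fold and 2.31-fold, and Tnfrsf19 rose from 33.0 ± 21.9 to 261 ± 47.2 in a probe set whose 2 others were not called. The median of that list was 0.17 while camera (adjusted p = 0.92) and fry (adjusted p = 0.0483) both gave the downward direction. Of 11 fetal liver genes Dlk1, an imprinted gene of hepatoblasts, rose from 2271 ± 569 to 5702 ± 370 (log2 change 1.35, and 0.83 with the mean of its probe sets, the other probe set not being called). Spink1, a trypsin inhibitor gene, fell from 163 ± 77.5 to 3.54 ± 5.16, with a camera adjusted p of 0.866 for the list. Of 14 acute phase and interferon genes Crp, for C-reactive protein, fell 4.04-fold and Saa3, a serum amyloid gene, rose 3.57-fold. The latter call was lost without Control_1192 or Control_1193 or Null_1191 or Null_1195 (adjusted p = 0.161, 0.113, 0.117 and 0.0910), with a pseudocount of 1 (0.0562) and without an intensity trend (0.0534). The list median was 0.07 where camera (0.92) and fry (0.0448) gave the downward direction. Of 17 glycolysis and hypoxia genes Hk2, a hexokinase, rose 2.30-fold and Bnip3, a mitophagy receptor, fell 1.94-fold (camera adjusted p = 0.896). Of 18 genes of endoplasmic reticulum stress Herpud1 and Dnajc3 fell 2.02-fold and 1.77-fold, the latter with 1 of 4 other probe sets called (camera adjusted p = 0.912). Of 12 p53 targets Cdkn1a, a cell cycle inhibitor, fell 1.64-fold (log2 change -0.71, and -0.46 with the mean of its probe sets, the other probe set not being called) and Zmat3 from 125 ± 8.20 to 74.9 ± 8.67 (camera adjusted p = 0.92 for the list). The call of Dnajc3 was lost without Control_1192, Control_1193 or Null_1191 (adjusted p = 0.120, 0.0986 and 0.0989), with embryo sex as a term (0.0695) and with quantile normalization (0.0535). That of Zmat3 was lost without Control_8, Control_1192 or Control_1193 or Null_1191 or Null_1195 (0.0844, 0.0878, 0.116, 0.0762 and 0.0550), with embryo sex (0.0540) and in the 4 arrays without Control_8 and Null_61 (0.0622). Of 16 granulocyte and monocyte genes the neutrophil proteases Mmp8 and Mmp9 fell 1.96-fold and 1.44-fold (camera adjusted p = 0.0827). The call of Mmp9 was lost without Control_8, Control_1192 or Control_1193 or Null_1191 or Null_1195 (0.0640, 0.126, 0.138, 0.115 and 0.0918), with embryo sex (0.0896) and with quantile normalization (0.0793), and its other probe set was not called. That list was called lower without Null_61 (adjusted p = 0.00302) or Control_1192 (0.0306), with array weights (0.0210) and in the 4 arrays without Control_8 and Null_61 (0.0193). Of 7 mesothelial genes Upk1b fell from 159 ± 24.2 to 75.4 ± 9.34, a call lost with the mean of its probe sets (log2 change -0.22, adjusted p = 0.214, none of the 3 others being called). Wt1 rose from 19.4 ± 8.77 to 49.0 ± 7.19 (camera adjusted p = 0.92 for the list), the latter lost without Control_8, Control_1192, Null_61, Null_1191 or Null_1195 (0.148, 0.161, 0.0820, 0.104 and 0.117), with quantile normalization (0.0644), a pseudocount of 1 (0.0699) and in the 4 arrays without Control_8 and Null_61 (0.145). No member of the cholangiocyte, lymphoid or pancreas lists, with 14, 11 and 9 measured genes, passed the test (camera adjusted p = 0.728, 0.824 and 0.857), and at an unadjusted p under 0.05 limma found 2 higher and 2 lower cholangiocyte genes, 1 higher lymphoid gene and 0 pancreas genes. Counted as adjusted over the list alone, the pericentral list had 2 higher and 5 lower genes, fetal liver 1 and 2, acute phase and interferon 2 and 2, glycolysis and hypoxia 2 and 3, endoplasmic reticulum stress 1 and 3, p53 targets 0 and 2, granulocytes and monocytes 0 and 2, mesothelium 1 and 1, and the cholangiocyte, lymphoid and pancreas lists 0 and 0. Afp, the gene of alpha-fetoprotein, had a log2 change of -0.06 and did not pass the test, with a signal near the top of the arrays' range as for Alb.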

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

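The tests of a lower hepatocyte share, of the markers of other cells, of the falls within 1 run of title numbers and with embryo sex as a term, of escaped recombination and of the Hnf4a probe sets' place were chosen after the results they bear on had been seen.

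A control probe set that no comparison of the report uses differed between the groups. AFFX-MURINE_b1_at, named for the mouse B1 repeat, read 712, 916 and 1037 in the controls and 1448, 2828 and 2653 in the nulls, a log2 change of 1.30 with a limma adjusted p of 0.0142. In all, 1 of the 64 control probe sets was higher and 7 were lower. Of the 7, 4 are named for mouse pyruvate carboxylase and went with Pcx. AFFX-PheX-3_at, named for a bacterial transcript, read 276, 227 and 194 in the controls and 67.4, 65.5 and 61.6 in the nulls (log2 change -1.44, adjusted p = 0.000296). AFFX-PheX-5_at and AFFX-PheX-M_at changed by -0.05 and -0.01 and were not called, so the difference lies in a single probe set. AFFX-r2-Bs-dap-5_at and AFFX-r2-Bs-dap-M_at changed by -0.67 and -0.96. Both were dim, at 29.4 to 34.2 and 34.2 to 37.0 in the controls. AFFX-r2-Bs-dap-3_at was not called, with a change of 0.55.

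The fall of the hepatocyte lists was set against a smaller share of hepatocytes in the null livers, an array batch and unequal sexes in the groups. A smaller share alone would lower all hepatocyte transcripts by 1 factor, but the log2 changes of the 36 plasma protein, coagulation, complement and apolipoprotein genes with all 6 values between 100 and 8000, away from the floor and the top of the range, had an SD of 1.10 beside a median standard error of 0.131. It would also raise the markers of other cells alike, if these cells kept their proportions to each other. The medians of the erythroid, megakaryocyte, endothelial and macrophage lists spanned 0.98, and the lowest was -0.46. None of these 4 shifts held with an estimated correlation, and the proportions were not measured, so the medians do not decide on a smaller share. Of 157 measured members of 8 hepatocyte lists 123 fell in the main fit, 124 within the 4 arrays of 1 run of title numbers, where the run is constant, and 118 with embryo sex as a term, so neither the runs alone nor the sexes alone can be the whole source. In those 4 arrays the controls were male and the nulls female, and the sex fit held no run term. With both terms 2021 of all genes fell, at 2 residual degrees of freedom. A sex effect that differs between the runs cannot be told apart from the group. For the 36 genes, the SD of 1.10 beside a median standard error of 0.131 argues against a smaller share alone as the source of the falls. A change in hepatocyte expression in the null livers remains as a hypothesis that was not tested directly. A smaller share as an additional part is not excluded. The controls carry 1 flanked allele with Cre, so the falls are relative to that state. How that state changes the size of the falls was not tested.

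The Hnf4a signal left in the null livers, 62.1% of the control level with a 95% interval of 47.7% to 80.8% in the lowest probe set, may come from cells that escaped recombination or from transcript outside the deleted part. Escaped hepatocytes with ordinary expression would carry their other transcripts too, yet 88 of the 157 measured members of 8 hepatocyte lists had a 95% upper bound below 47.7% of the control level. That count speaks against escape as the whole source only if an escaped cell carries no more Hnf4a transcript than a control cell. By the strain label an escaped null cell keeps both alleles intact, and a recombined control cell keeps only the unflanked one. A smaller share of escaped cells could then leave the same signal, so the count does not decide on escape. Whether the probe sets lie outside the deleted part stays open, since their places in the transcript were not used here; the log2 changes of the 4 probe sets differ by at most 0.21.

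Of the 283 genes that rose, 4 had values at or below 0 in all 3 controls: Meis3, Hcrt and, named after their values were seen, Gm34303 and 1700120B22Rik; the first 3 had control means below -100. A candidate explanation is a mismatch signal that was subtracted too strongly in the controls because the mismatch probes bound a transcript that fell. Of the 19 probe sets with a mean below -100 over the 6 arrays, 63.2% were less negative in the nulls, with an exact (Clopper-Pearson) 95% interval of 38.4% to 83.7%, and 55.6% of all probe sets were higher there. With so few probe sets, a mismatch signal and a rise of the transcripts cannot be told apart.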

How the results depend on the processing

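The calls of the 4 arrays without Control_8 and Null_61 read in that pair, and the fit with both the number run and embryo sex, were chosen after seeing the data.

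Falls outnumbered rises in each setting. The 283 rises became 617 with quantile normalization, 613 with array weights, 747 with the number run as a block, 734 with the run and embryo sex together (2 residual degrees of freedom), 170 with embryo sex alone, 54 at a change of at least 2-fold and 658 when probe sets were counted. The 1428 falls became 683 at a change of at least 2-fold and 2501 when probe sets were counted, and were 1102 to 2021 in the other settings that kept all arrays and genes. Leaving out 1 array gave 98 to 558 rises and 906 to 1689 falls. The fold limit and the count of probe sets act by their construction, and the block acts through the residual spread. A left-out array leaves fewer samples, but that does not account for the larger counts without Null_61 (558 rises and 1689 falls). For those counts and for the other settings the cause was not tested. The 21 called lists were 19 to 22 in every setting except the estimated correlation, with 8, whose wider spread of a list's mean is part of its construction. Hnf4a lay at -0.72 to -0.31 when 1 array was left out, and passed the threshold without Null_1195 and, at -0.56 (adjusted p = 0.037), as the mean of its probe sets; its adjusted p ran from 0.00589 to 0.452 over the alternatives, and the cause was not tested. No named gene and no list reversed its direction and call in any alternative. Outside the left-out arrays, 98 values were followed, namely the genes of the naming rule and 3 further Hnf4a probe sets. The main Hnf4a probe set is treated above and was left out. Of the 98, 12 lost their call with embryo sex, 9 with quantile normalization and 7 in the 4 arrays without Control_8 and Null_61. The number was 6 without the intensity trend, 6 with a pseudocount of 1 and 2 with centred medians. It was 0 with array weights, the number run as a block or a pseudocount of 100. The fold limit leaves each adjusted p as it is, so losses at that limit were not counted. Named genes that changed less than 2-fold, such as Timd4, Pf4 and Birc5, are not called under it. With the mean of probe sets 4 of 95 values lost their call, and above the median level 0 of the 89 that were tested. Calls were also gained among these values, by 7 with the number run as a block, 4 each with array weights and the mean of probe sets, and 3 each with quantile normalization and above the median level. Each gene that lost a call in these counts is named with its values in the report. The number run as a block moves no log2 change, since the runs hold equal shares of both groups, and acts only through the residual spread. Of the lists, the endothelial one lost its call with quantile normalization (adjusted p = 0.0541), above the median level (0.163), with the mean of probe sets (0.0598) and with embryo sex (0.0554), and the immediate early one with quantile normalization (0.0541) and above the median level (0.0657). Of the genes called in the 4 arrays other than Control_8 and Null_61, 367 of 424 rises (86.6%) and 1525 of 1565 falls (97.4%) had the same direction in Null_61 against Control_8, where 51.4% and 48.5% of all genes had it. Quantile normalization put the median log2 change of all genes at 0.06 in place of 0.01. No paired analysis was possible because the groups share no title number. Signal over background limits the genes that fell: in 14 of the 1428 all 3 nulls lay at or below 0, and falls to values just above 0 depend on the pseudocount as well, with log2 changes of -7.66 and -4.27 for F13b and -9.03 and -4.44 for Hsd17b13 at pseudocounts of 1 and 100.

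In the 10 splits of the 6 arrays into 3 and 3, the real split gave 283 rises, 1428 falls and 21 lists, and the highest of the others gave 1, 1 and 15. Only 1 split, the real one, gave as many of each, and 10 splits are too few for a share under 0.05.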

Other observations

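The tests of the imprinted genes and of the neighbours of Hnf4a were set out before their results were seen, but the reading of both was changed afterwards; the imprinted genes named below, except Nnat and Dlk1, were chosen after their values were seen.

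Pyruvate carboxylase, which makes oxaloacetate for gluconeogenesis, was measured a further 4 times by control probe sets along its transcript. Their log2 changes were -3.22 for the 3' probe set, -2.17 for the 5' one and -1.93 and -1.54 for those between, each with an adjusted p under 0.05, beside -3.10 for Pcx.

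Imprinted genes, expressed from 1 parental allele, moved in both directions. Besides Nnat and Dlk1, whose other probe set was not called, Meg3, a noncoding RNA gene next to Dlk1 and expressed from the other parental allele, rose from 1812 ± 154 to 4366 ± 1697 (log2 change 1.19, limma adjusted p = 0.0148), and Igf2r, the clearance receptor of insulin-like growth factor II, rose from 618 ± 105 to 1155 ± 290 (0.85, adjusted p = 0.0326). Cdkn1c, a growth-restraining cell cycle inhibitor, fell from 1111 ± 334 to 442 ± 113 (-1.25, adjusted p = 0.0177), and Slc38a4, an amino acid transporter gene of hepatocytes, fell from 1980 ± 246 to 820 ± 146 (-1.25, adjusted p = 0.00112). The hypothesis that imprinted genes rose together was tested on the 24 measured members of a list without Nnat and Dlk1. Camera gave a p of 0.769 and the median log2 change was -0.06, with 2 members called in each direction. A p that misses the threshold had been set to count against the hypothesis, which was too strict, since such a p excludes nothing; a shared rise of part of the class may remain, and the falls of Cdkn1c and Slc38a4 speak against a rise of all of it.

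A segment of the donor strain around the flanked allele could change genes near Hnf4a whatever the state of the protein. Of the 100 measured genes nearest to Hnf4a on chromosome 2, in the gene order of GRCm38.p6, 11 were called (11%, exact 95% interval 5.62% to 18.8%), 3 higher and 8 lower, against 9.40% of the other genes (one-sided Fisher's exact p = 0.339). Nnat lies within that stretch, 38 measured genes away. The share had been set to count against the segment at under 1.5 times that of the other genes, but the interval reaches beyond that, so a small effect of a segment and none cannot be told apart.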
